A study of Drosophila melanogaster with 54 samples.

How the data were processed

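The deposited files are 4 tables of counts per gene, 1 each for St5, St7, St15 and S2 cells, with 1 column per library and no pooling by the authors. Per the submitters' processing notes the reads were mapped to the genome build dm6. The aligner, the counting program, the annotation release and any filter are not given in the sources used here. Per the labels' protocols, polyA RNA went through the TruSeq Stranded mRNA kit, and whether counting used the strand is not stated. The values were checked as whole numbers whose sums differ between libraries, so they were used as counts with no change of unit.

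Per the labels, embryos with lowered mof were progeny of mothers carrying a maternal alpha-tubulin Gal4 driver and an RNA interference stock, crossed to siblings. St15 embryos were sorted by Sxl-GFP, which marks females. S2 cells received 10 ug of dsRNA per 1e6 cells for 3 days at 25 °C, with dsRNA against GFP as control. The genotype text of St15 mof libraries says control but carries the mof stock number, and titles and mof counts were followed. The St5 control females, whose genotype field names the mof stock, were kept as controls on their titles, names and mof counts.

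Each table held 17558 genes. At St7, St15 and S2, 17252 were matched to the reference annotation of Ensembl release 115 by gene ID, which covered 94.6, 95.4 and 95.6% of counts. The St5 table is named by symbol, and 12887 were matched by current symbol, 3603 by locus tag and 839 by a unique synonym, while 113 were ambiguous and 116 unmatched. Chromosomes were thus known for 98.7% of St5 counts. Autosomes are chromosomes 2, 3 and 4. Of the list members, nos was not matched.

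Each table was fitted alone, because stage and table cannot be told apart. edgeR 4.0.16 was run in R 4.3.3 with TMM scaling, filterByExpr on the groups, 1 mean per group, robust quasi-likelihood fits and no replicate block. Adjusted p is Benjamini-Hochberg over all genes tested, and genes under 0.05 passed. The 13 comparisons are mof against control in males and females of each stage and in S2 cells, male against female in the controls of each stage, and the difference of the mof effect between sexes at each stage. Genes tested numbered 9103 at St5, 8717 at St7, 10684 at St15 and 9676 in S2 cells.

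The 30 gene lists and the 6 chromosome arms were tested with camera of limma 3.58.1 at a preset correlation of 0.01, for lists with at least 5 tested members, and again with the correlation estimated and with fry. The lists are Hox genes, MSL and roX genes, NSL complex genes, RNA interference genes, Y-linked genes, anterior-posterior segmentation genes, apoptosis and p53 response genes, cell cycle genes, chitin and tracheal tube genes, cuticle protein genes, cytoplasmic ribosomal protein genes, dorsoventral and germ layer genes, early zygotic cellularization genes, fat body and hemocyte genes, glial genes, glycolysis genes, heat shock genes, innate immune genes, maternally supplied egg regulators, midgut genes, mitochondrially encoded genes, muscle genes, neuronal genes, ovarian follicle cell genes, oxidative phosphorylation genes, oxidative stress and detoxification genes, pole cell and germline genes, salivary gland genes, sex determination genes and strain marker genes. They were written from general knowledge.

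For each library the log2 ratio of counts on X to counts on autosomes was computed. The 2 groups of each of 7 mof comparisons were compared by a two-sided exact permutation test, with Benjamini-Hochberg over the 7. Beside it stands the median log2 fold change of tested X genes less that of autosomal genes. A fold against a group with 0 counts is given as a lower bound, from a floor of 3 counts over the group. Intervals on shares of counts are Wilson intervals. For the difference in X ratio of the mof effect between sexes, sex labels were permuted within each treatment. That permutation supposes no sex difference in either treatment, so its p does not test the difference in mof effect alone.

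Genes were named by a rule fixed beforehand. For each mof comparison it takes the 10 risen and 10 fallen genes with the largest changes among genes that passed, had a mean log2 CPM of at least 2 and separated the libraries of the groups. It adds up to 4 passing members per list and direction, and mof, roX1, roX2, msl-2 and Sxl everywhere. For the other comparisons it takes 5 per direction. The report prints a part of these for length.

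Agreement between comparisons is the Spearman correlation of log2 fold changes over genes tested in the 2, in 12 pairs that share no library. Alternatives fixed beforehand were DESeq2 1.42.0, RLE scaling, TMM scaling on autosomal genes, no low count filter, at least 10 CPM, the replicate number as a block, fits without the robust option, only the 2 groups compared, leaving out each library in turn, and, for the X ratio, leaving out chromosome 4 or the 50 genes with the most counts. Alternatives chosen after seeing the data left out libraries that stood apart or added the mean log2 CPM of the egg regulators as a covariate. Group labels were also split in other ways, at most 100 per comparison, to see what groups at random give.

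The code was tested on simulated data. Counts were drawn for every library from the mean level of each gene over the table and its fitted dispersion. Such counts hold no differences of age or sex between libraries. For the St15 male comparison, 79% of 2-fold and 87% of 4-fold changes put into them were recovered. In St5 females these were 4 and 46%. An X factor of 0.75 (-0.42 in log2) came back as -0.42. Values were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. All 54 libraries were used. Read mapping, splicing, alleles and other data of the study were not analysed here.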

Results

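The data are counts of polyA RNA from Drosophila melanogaster embryos and S2 cells in which mof was targeted by RNA interference, beside controls. mof (dm6 chromosome X, 5873840 to 5876853) encodes the acetyltransferase of the male-specific lethal (MSL) complex, which acts on the male X, and it also works in other complexes in both sexes. There were 54 libraries in 14 groups. Blastoderm embryos of nuclear cycle 14 (St5) gave 4 control males, 4 mof males, 2 control females and 2 mof females. Gastrulating embryos (St7) gave 7 control males, 6 mof males, 6 control females and 4 mof females. Embryos of 14 to 16 h (St15) gave 3 control males, 3 mof males, 3 control females and 4 mof females. S2 cells gave 3 libraries per treatment. In embryos, any difference in background between the mof and control stocks cannot be told apart from mof depletion. Each St5 or St7 library is 1 embryo and each St15 library a pool of 25, while nothing in the labels says that the S2 libraries came from separate cultures. Depth (M, counts in units of 1e6) was 28.3 to 41.5 M at St5, 5.50 to 10.02 M at St7, 19.02 to 38.1 M at St15 and 20.5 to 38.8 M in S2 cells.

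Values in parentheses after a gene name are edgeR log2 fold changes ± standard error. The standard error is not fitted by edgeR but is the absolute log2 fold change over the square root of its F statistic. Adjusted p after a run of genes is the largest of the run, from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Levels are counts per 1e6 counted (CPM), mean ± SD over the libraries of a group. Genes whose span overlaps another protein-coding gene carry its name in square brackets, and their values are uncertain because the use of strand in counting is not stated. Overlaps with noncoding RNA genes are not listed. Gene lists were fixed before the data were examined. For each list the counts passing are followed by the counts adjusted over the list alone (written as alone) and by camera's adjusted p. Where males are compared with females, rose and fell mean higher and lower in males.

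mof RNA fell in every embryo group. It stood at 2.72 ± 1.42 CPM (range 1.46 to 4.51) in St5 mof males against 321 ± 68.2 (268 to 414) in control males (-6.68 ± 0.40), and at 1.08 ± 0.241 (0.912 to 1.25) against 604 ± 103 (531 to 677) in St5 females (-9.07 ± 0.64). At St7 the levels were 9.10 ± 8.93 (2.39 to 25.1) against 136 ± 45.3 (52.8 to 202) in males (-3.86 ± 0.44) and 11.4 ± 4.72 (7.02 to 18.01) against 37.7 ± 8.18 (27.7 to 48.4) in females (-1.65 ± 0.49). At St15 they were 2.55 ± 0.417 (2.17 to 3.00) against 25.4 ± 11.5 (18.5 to 38.7) in males (-3.30 ± 0.25) and 2.82 ± 0.304 (2.57 to 3.23) against 11.1 ± 0.124 (10.97 to 11.2) in females (-1.92 ± 0.22). The edgeR adjusted p of these was at most 0.0144, in St7 females. In S2 cells mof stood at 61.2 ± 11.3 CPM (50.1 to 72.7) after mof dsRNA and 69.4 ± 3.10 (65.9 to 71.8) after GFP dsRNA (-0.17 ± 0.16, edgeR adjusted p = 0.491), which did not pass.

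**Figure D1:**
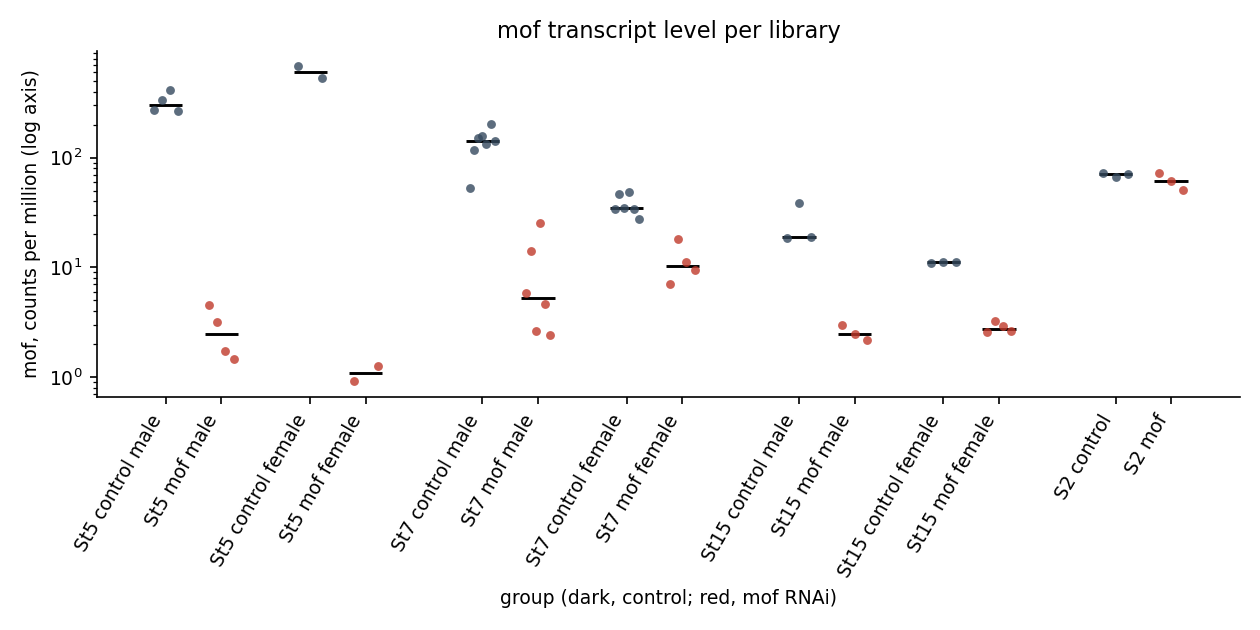
CPM of mof (log axis) in each library, by group, with dark points for control, red points for mof RNA interference and a line at the group median. The embryo groups separate by treatment and the S2 groups do not.

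**Figure D2:**
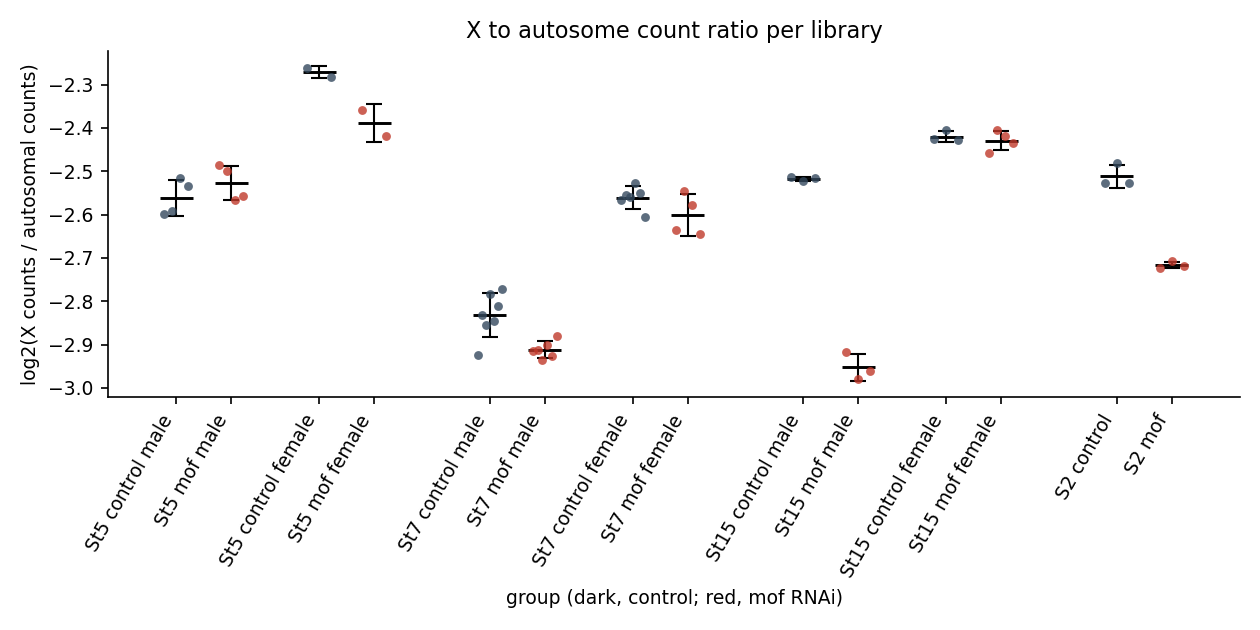
log2 ratio of counts on X genes to counts on autosomal genes in each library, by group (dark control, red mof), with a horizontal bar at the mean and error bars of 1 SD. The largest gaps lie at St15 males and S2 cells.

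What changed in blastoderm males when the mother's mof RNA was depleted? In St5 males 593 genes rose and 667 fell of 9103 tested (edgeR's quasi-likelihood test). Glycolysis enzymes and oxidative phosphorylation genes were among the genes that rose. The transcription factors CrebA, Ptx1, trh and peb and the stress regulator Xrp1 were among those that fell. Of the X genes that passed, 131 rose and 81 fell, but without mof males 1 and 2 these were 47 and 56, and 191 and 195 when control male 3 was left out as well. The mof libraries labelled male 1 and 2 held 3 and 0 counts of Y-linked genes, where the other 6 St5 male libraries held 198 to 383. The sex of these 2 embryos is in doubt, so the comparison may mix the sexes.

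The largest rises were Hsp70Bb (5.98 ± 0.88), CG15047 (5.65 ± 0.64 [Bx]), narya (5.26 ± 0.59 [CG32533]), CG32354 (4.95 ± 0.47 [Exo70]), Argk1 (3.48 ± 0.24) and Pxt (2.35 ± 0.18) (largest adjusted p = 0.00300). Argk1, an arginine kinase, went from 6.88 ± 1.23 to 66.3 ± 9.43 CPM. Hsp70 genes are near-identical copies, so the copy named here and below is uncertain. The transgene marker w (3.93 ± 0.75 [kirre]) (adjusted p = 0.00791) rose too, but it stood at 3.67 CPM in mof male 1 and at 92.5 to 110 in the other 3. The largest falls were CG13532 (at least 744-fold lower), CG14696 (-5.79 ± 1.36), CG9119 (-5.02 ± 0.66 [mwh]), GluRIIA (-3.96 ± 1.01 [CG14017]) and Ptx1 (-3.77 ± 0.62) (largest adjusted p = 0.0249). Also lower were CrebA (-2.57 ± 0.69), Xrp1 (-2.58 ± 0.40), Irbp (-2.13 ± 0.44), trh (-1.96 ± 0.44), peb (-1.85 ± 0.45) and pip (at least 124-fold lower [fal]) (largest adjusted p = 0.0302).

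Of the glycolysis genes, 6 of 11 rose and 0 fell (alone 7 and 0), camera up with adjusted p = 2.40e-06 and adjusted p = 0.173 with an estimated correlation. Examples are Hex-A (2.29 ± 0.39), Pfk (2.01 ± 0.33) and Gapdh1 (1.47 ± 0.18) (largest adjusted p = 0.00468). Of the oxidative phosphorylation genes, 16 of 69 rose and 1 fell (alone 21 and 1), camera up with adjusted p = 2.32e-07 and adjusted p = 0.537 with an estimated correlation, with ND-AGGG (1.07 ± 0.19) and ND-B16.6 (1.02 ± 0.18 [CG3847]) (largest adjusted p = 0.00578). Of the cytoplasmic ribosomal protein genes, 4 of 87 rose and 0 fell (alone 53 and 1), camera up with adjusted p = 1.06e-12 and adjusted p = 0.537 with an estimated correlation. The maternally supplied egg regulators include gnu and plu, which drive the first nuclear divisions, and 7 of 25 rose and 0 fell (alone 8 and 2), camera up with adjusted p = 0.00124 and adjusted p = 0.537 with an estimated correlation. These were gnu (1.81 ± 0.32), tor (1.72 ± 0.24), gcl (1.24 ± 0.21 [CG30356]) and plu (1.17 ± 0.18) (largest adjusted p = 0.00573) and 3 others. Of the pole cell and germline genes, 5 of 12 rose and 0 fell (alone 5 and 1), camera up with adjusted p = 0.0137 and adjusted p = 0.520 with an estimated correlation, with spn-E (1.09 ± 0.17 [Pbp45]) and aub (0.69 ± 0.15 [TTLL4A]) (largest adjusted p = 0.0137). Of the cell cycle genes, 4 of 24 rose and 0 fell (alone 4 and 0), camera up with adjusted p = 0.0137 and adjusted p = 0.170 with an estimated correlation, with RnrL (0.996 ± 0.18) and PCNA (0.71 ± 0.11) (largest adjusted p = 0.00570). Of the salivary gland genes, 0 of 6 rose and 2 fell (alone 0 and 4), camera down with adjusted p = 0.00203 and adjusted p = 0.170 with an estimated correlation.

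Of the MSL and roX genes, 1 of 8 rose and 1 fell (alone 1 and 1), camera adjusted p = 0.366, with a median of 0.12 and a mean of -0.64, mof being a member. msl-1 (0.47 ± 0.13) (adjusted p = 0.0404) rose, and roX1 (0.47 ± 0.26, adjusted p = 0.243) and roX2 (0.029 ± 0.64, adjusted p = 0.988) did not pass. Sxl stood at 469 and 400.0 CPM in mof males 1 and 2, and its edgeR value (2.43 ± 0.71, adjusted p = 0.0428) was -0.065 without them. Of the oxidative stress and detoxification genes, 5 of 20 rose and 1 fell (alone 5 and 1), camera adjusted p = 0.219, with a median of 0.089 and a mean of -0.0075. Gclc (2.05 ± 0.36) and GstE1 (1.72 ± 0.14 [GstE10]) (largest adjusted p = 0.00534) rose among them.

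X genes had a median change 0.14 above that of autosomal genes, with a median of 0.11 and a mean of -0.087 (camera adjusted p = 0.117). It was 0.067 above without mof males 1 and 2 (camera adjusted p = 0.647), and 0.067 above when control male 3 was left out as well (camera adjusted p = 0.344). The log2 ratio of X to autosomal counts was -2.53 ± 0.040 in mof males and -2.56 ± 0.042 in controls (two-sided exact permutation p = 0.314, adjusted p = 0.389 over 7 comparisons). Libraries of the 2 groups did not overlap for 1704 of the 9103 genes tested, or 18.7%, where chance gives 2.86%. The count of 1260 genes was 549, 509 and 2461 without control males 1, 2 and 3, 827 and 791 without mof males 2 and 3, 586 without mof males 1 and 2, and 2245 when control male 3 was left out as well. It was 2058 with DESeq2, 752 at 10 CPM or more, 741 with the replicate block and 823 with only the 2 groups. Rises outnumbered falls without mof male 3 (400 and 391), without mof male 4 (447 and 408), with the block (412 and 329), at 10 CPM or more (380 and 372) and with scaling on autosomal genes (663 and 648).

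**Figure D3:**
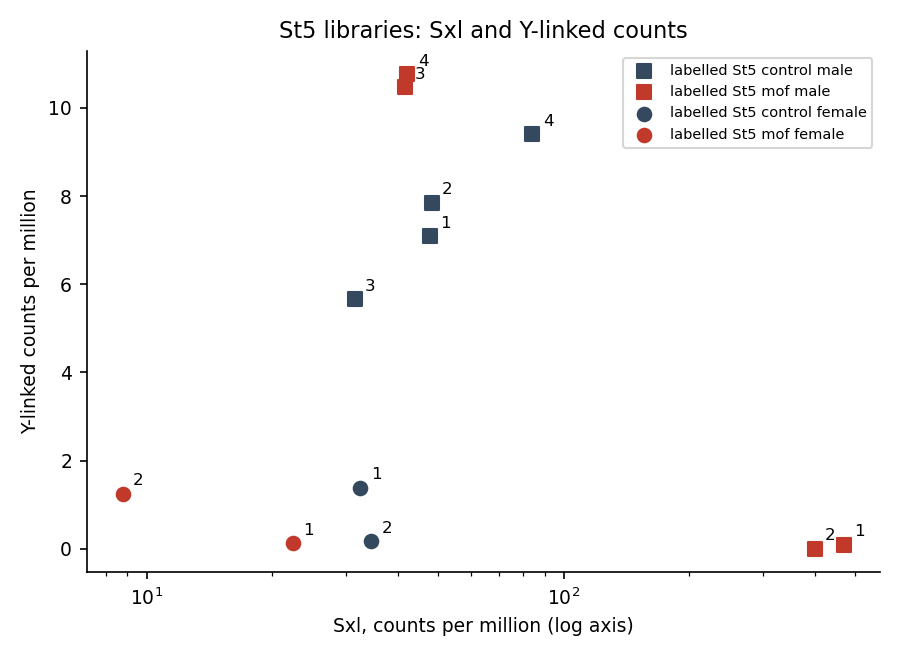
CPM of Sxl (log axis) against CPM of all Y-linked genes for the 12 St5 libraries, with squares for libraries labelled male, circles for female, dark for control and red for mof. The squares at high Sxl with almost no Y-linked counts are mof males 1 and 2.

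Did the same depletion change RNA in blastoderm females? In St5 females 204 genes rose and 164 fell, with 2 libraries per group. Early zygotic genes such as halo and Z600 and the cell death gene rpr rose. CrebA, Xrp1 and the septate junction gene Gli fell. From control to mof females the mean log2 CPM went from 2.75 ± 0.031 to 3.65 ± 0.46 over segmentation genes, from 6.75 ± 0.15 to 7.38 ± 0.088 over mitochondrially encoded genes and from 6.99 ± 0.14 to 6.67 ± 0.23 over egg regulators, and control males stood at 5.49 ± 0.58, 7.51 ± 0.14 and 4.38 ± 0.25. Age within the stage is not recorded. mof female 2 held 52 counts of Y-linked genes (1.25 CPM, 95% Wilson interval 0.955 to 1.64), and mof female 1 held 5. The genotype field of the control females names the mof stock, while their titles say control and their mof level was high (range 531 to 677 CPM).

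The highest rises were narya (6.06 ± 0.88 [CG32533]), w (5.05 ± 1.13 [kirre]), rpr (5.04 ± 0.93), Art2 (4.37 ± 0.81), Obp99a (4.30 ± 0.63), egr (3.12 ± 0.64) and Ldh (3.07 ± 0.59) (largest adjusted p = 0.0278). rpr activates cell death and egr is a ligand of the tumour necrosis factor family. The deepest falls were CG13532 (at least 1146-fold lower), CG14696 (-10.93 ± 2.53), CG14131 (-10.01 ± 1.46 [Pi3K68D]), CrebA (-6.54 ± 1.13), Gli (-5.23 ± 0.93), Xrp1 (-5.04 ± 0.64), Vdup1 (-4.71 ± 0.92), moody (-2.64 ± 0.63 [CG4313]) and peb (-2.56 ± 0.64) (largest adjusted p = 0.0437). Of the early zygotic cellularization genes, 7 of 19 rose and 0 fell (alone 9 and 0), camera up with adjusted p = 2.94e-10 and adjusted p = 0.0938 with an estimated correlation. halo went from 43.2 ± 0.0148 to 279.6 ± 126 CPM, beside Traf4 (3.56 ± 0.56), Z600 (3.46 ± 0.63 [gdl, gdl-ORF39]) and Bro (2.04 ± 0.50) (largest adjusted p = 0.0414). Of the anterior-posterior segmentation genes, 3 of 24 rose and 0 fell (alone 17 and 0), camera up with adjusted p = 1.01e-08 and adjusted p = 0.507 with an estimated correlation, with kni (1.82 ± 0.41), Kr (1.81 ± 0.35 [CG9380]) and hkb (1.39 ± 0.30) (largest adjusted p = 0.0275). Of the dorsoventral and germ layer genes, 2 of 22 rose and 1 fell (alone 7 and 1), camera up with adjusted p = 0.0174 and adjusted p = 0.572 with an estimated correlation, with twi (1.44 ± 0.26 [CG9897, CG9896]) and vnd (1.63 ± 0.40 [spdi]) (largest adjusted p = 0.0418) up. Among cytoplasmic ribosomal protein genes, 2 of 87 rose and 0 fell (alone 77 and 0), camera up with adjusted p = 3.82e-27 and adjusted p = 0.507 with an estimated correlation, with RpL15 (0.87 ± 0.21) and RpS3A (0.74 ± 0.19) (largest adjusted p = 0.0479). Of the mitochondrially encoded genes, 1 of 13 rose and 0 fell (alone 7 and 0), camera up with adjusted p = 3.88e-05 and adjusted p = 0.533 with an estimated correlation. For glial genes, 0 of 7 rose and 1 fell (alone 0 and 4), camera down with adjusted p = 0.0169 and adjusted p = 0.499 with an estimated correlation. roX1 (1.31 ± 0.38, adjusted p = 0.0782), msl-2 (1.74 ± 0.83, adjusted p = 0.269) and Sxl (-1.08 ± 0.98, adjusted p = 0.590) did not pass, and roX2 had 0 counts (under a floor of 3).

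Of the X genes 21 of 1510 rose and 38 fell (alone 21 and 36), and their median was 0.17 below that of autosomal genes (camera adjusted p = 0.0381, adjusted p = 0.507 with an estimated correlation). The X to autosome ratio was -2.39 ± 0.043 against -2.27 ± 0.014, lower by 7.76%, and this design cannot reach p under 0.05 (two-sided exact permutation p = 0.333, its smallest, adjusted p = 0.389). The libraries of the groups stood apart for 5468 of the genes tested, or 60.1%, where chance gives 33.3%. The count of 368 genes was 44 and 108 without control females 1 and 2, 225 and 43 without mof females 1 and 2, 989 with DESeq2, 190 with the replicate block, 260 with maternal RNA as a covariate and 1965 when only the 2 groups entered the fit. Falls outnumbered rises without control female 2 (64 and 44) and with only the 2 groups (1022 and 943), and on X rises outnumbered falls without mof female 1 (14 and 9). The X median lost its call without control female 2 (-0.094, camera adjusted p = 0.114) and without mof female 2 (-0.10, camera adjusted p = 0.188), and also with no low count filter (-0.031, camera adjusted p = 0.0749), only the 2 groups (-0.18, camera adjusted p = 0.105) and the maternal covariate (-0.12, camera adjusted p = 0.316).

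How did control males and females differ at the blastoderm stage? The libraries labelled male held far more segmentation and Hox RNA, and those labelled female more egg RNA and stg, the phosphatase that starts mitosis. The egg transcript bcd stood at 246 to 265 CPM in the 2 female and 3.25 to 14.6 in the 4 male controls. Males exceeded females for 3139 genes and fell below for 2503, and 82.4% of the genes passing were autosomal. Control female 1 held 40 counts of Y-linked genes (1.38 CPM, 95% Wilson interval 1.01 to 1.88), and control female 2 held 6.

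Segmentation regulators were much higher in males: knrl (at least 505-fold higher), Blimp-1 (at least 476-fold higher), pdm2 (at least 443-fold higher [Nepl7]), opa (9.28 ± 1.68) and en (at least 6.63-fold higher) (largest adjusted p = 0.00899). Of the anterior-posterior segmentation genes, 22 of 24 rose and 1 fell (alone 22 and 1), camera up with adjusted p = 8.23e-10 and adjusted p = 0.182 with an estimated correlation. For Hox genes, 6 of 8 rose and 0 fell (alone 7 and 0), camera up with adjusted p = 0.0386 and adjusted p = 0.448 with an estimated correlation, with Dfd (at least 75.6-fold higher), Antp (at least 31.6-fold higher) and Ubx (5.86 ± 1.61) (largest adjusted p = 0.00875). Dorsoventral and germ layer genes went the same way, as 18 of 22 rose and 1 fell (alone 18 and 1), camera up with adjusted p = 3.14e-07 and adjusted p = 0.182 with an estimated correlation, with sog (7.14 ± 0.71) and htl (8.05 ± 1.96) (largest adjusted p = 0.00407). Of the early zygotic cellularization genes, 13 of 19 rose and 2 fell (alone 14 and 2), camera up with adjusted p = 6.93e-06 and adjusted p = 0.139 with an estimated correlation, with Traf4 (8.48 ± 0.63) and halo (5.24 ± 0.34) (largest adjusted p = 1.29e-06). Of the maternally supplied egg regulators, 0 of 25 rose and 20 fell (alone 0 and 20), camera down with adjusted p = 2.36e-09 and adjusted p = 0.176 with an estimated correlation, with bcd (-5.06 ± 0.86), swa (-5.26 ± 0.69) and gcl (-4.12 ± 0.26 [CG30356]) (largest adjusted p = 0.000385). Among pole cell and germline genes, 1 of 12 rose and 9 fell (alone 1 and 9), camera down with adjusted p = 1.73e-07 and adjusted p = 0.139 with an estimated correlation, with osk (-4.13 ± 0.46) (adjusted p = 1.64e-05). Among cell cycle genes, 8 of 24 rose and 11 fell (alone 8 and 12), camera down with adjusted p = 0.00794 and adjusted p = 0.139 with an estimated correlation, with stg (-5.11 ± 0.27), dap (-3.49 ± 0.39) and CycB (-2.91 ± 0.12) (largest adjusted p = 1.67e-05). Among glycolysis genes, 2 of 11 rose and 8 fell (alone 2 and 8), camera down with adjusted p = 0.000343 and adjusted p = 0.207 with an estimated correlation, with Hex-A (-6.38 ± 0.48) and Eno (-3.76 ± 0.25 [Rrp40]) (largest adjusted p = 1.35e-06). For heat shock genes, 1 of 10 rose and 5 fell (alone 1 and 5), camera down with adjusted p = 0.0317 and adjusted p = 0.221 with an estimated correlation, with Hsp27 (-5.53 ± 0.42) and Hsp83 (-2.49 ± 0.33 [CG14966]) (largest adjusted p = 6.04e-05).

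For dosage compensation, roX1 (4.68 ± 0.42 [ec]), roX2 (at least 12.2-fold higher), msl-2 (6.09 ± 0.94) and kl-3 (at least 13.3-fold higher) (largest adjusted p = 0.0353) were higher in males, msl-1 (-1.92 ± 0.16) (adjusted p = 2.26e-06) was lower, and mof (-0.71 ± 0.37, adjusted p = 0.112) and Sxl (0.80 ± 0.86, adjusted p = 0.430) did not pass. The submitters called the sex of St5 and St7 embryos from msl-2, Sxl, tra and tra2 in these same libraries, so these 4 genes are no independent evidence. The female libraries also held far more egg RNA, so age and sex cannot be told apart in the roX1 and X values of this paragraph. At St7 roX1 was lower in control males than in control females. Of the X genes 338 of 1510 rose and 577 fell (alone 336 and 574), with a median 0.73 below that of autosomal genes (camera adjusted p = 0.00147, adjusted p = 0.176 with an estimated correlation). The X to autosome ratio was lower in males by 0.29 (two-sided exact permutation p = 0.133, and the smallest possible p is 0.0667). Groups did not overlap for 6443 of the genes tested, or 70.8%, where chance gives 13.3%, and with RLE scaling the median of all genes moved by 0.13. Without control female 1 the genes higher and lower were 2037 and 2100, and without control female 2 they were 1932 and 1967.

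Did the effect of mof depletion differ between blastoderm males and females? The test of the difference found 11 genes, 5 higher and 6 lower in males. Pxt (2.34 ± 0.29) (adjusted p = 0.0167) was higher in males, and halo (-2.20 ± 0.36) (adjusted p = 0.0476) was lower in males. The difference for mof was 2.39 ± 0.59 (edgeR adjusted p = 0.125), and Sxl (3.51 ± 1.23, adjusted p = 0.242) and roX1 (-0.84 ± 0.46, adjusted p = 0.424) did not pass. For glycolysis genes, 0 of 11 rose and 0 fell (alone 7 and 1), camera up with adjusted p = 1.35e-06 and adjusted p = 0.139 with an estimated correlation. X genes had a median 0.37 above that of autosomal genes (camera adjusted p = 0.000149, adjusted p = 0.139 with an estimated correlation). The exact permutation p for the difference in X ratio was 0.351. It came from sex labels permuted within each treatment, so sex differences shared by the treatments enter it too. The 11 genes were 0, 3 and 140 without control males 1 to 3, and 3, 2, 3 and 1 without mof males 1 to 4. They were 337 with DESeq2, 6 with autosomal scaling, 3 at 10 CPM or more and 0 with the replicate block.

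Which genes followed mof depletion in gastrulating males? In St7 males 866 genes rose and 1330 fell of 8717 tested, but the balance was near even with scaling on autosomal genes (1156 and 1202), at 10 CPM or more (835 and 849) and without control male 4 (1207 and 1214). Of 22 cell cycle genes 16 rose, and so did 4 genes whose products act with mof on the male X. Hml, Lsp2 and cac, known from blood cells, fat body and neurons, fell. Of 1444 X genes 284 fell and 50 rose, and 201 of the fallen and 31 of the risen passed in the same direction in St7 females.

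The largest rises were Hsp70Bb (3.47 ± 0.51), CG11263 (2.72 ± 0.63), Argk1 (2.56 ± 0.25), GILT3 (1.80 ± 0.28) and tei (1.14 ± 0.26 [CG13337, CG18368]) (largest adjusted p = 0.00348). The largest falls were CG18586 (-4.69 ± 0.30 [CG5568]), Inx5 (-3.32 ± 0.64), Pask (-3.08 ± 0.31), Rsph3 (-2.70 ± 0.29) and Sply (-2.43 ± 0.30) (largest adjusted p = 0.000908). Inx5 encodes a gap junction protein. Of the cell cycle genes, 16 of 22 rose and 0 fell (alone 19 and 0), camera up with adjusted p = 8.14e-08 and adjusted p = 0.192 with an estimated correlation, with aurA (0.74 ± 0.21 [CG12213]), stg (0.39 ± 0.093), CycA (0.37 ± 0.062 [CG7264]) and Mcm5 (0.35 ± 0.10) (largest adjusted p = 0.0117). Of the MSL and roX genes, 4 of 8 rose and 1 fell (alone 4 and 1), camera adjusted p = 0.328, with a median of 0.19 and a mean of -0.30. msl-1 (0.46 ± 0.13), Clamp (0.44 ± 0.084 [CG42748]), msl-3 (0.27 ± 0.074 [form3]) and mle (0.26 ± 0.090) (largest adjusted p = 0.0350) rose, and roX1 (0.11 ± 0.13, adjusted p = 0.540), roX2 (-0.22 ± 0.37, adjusted p = 0.697), msl-2 (0.12 ± 0.12, adjusted p = 0.508) and Sxl (0.15 ± 0.14, adjusted p = 0.437) did not pass. For muscle genes, 3 of 12 rose and 0 fell (alone 3 and 0), camera up with adjusted p = 0.0430, adjusted p = 0.192 with an estimated correlation and adjusted p = 0.0605 with the replicate block, with Mef2 (0.58 ± 0.14) and how (0.48 ± 0.13) (largest adjusted p = 0.0106). For Hox genes, 2 of 8 rose and 0 fell (alone 3 and 1), camera adjusted p = 0.117, with lab (0.94 ± 0.23) and Antp (0.26 ± 0.094) (largest adjusted p = 0.0448). Of the apoptosis and p53 response genes, 4 of 16 rose and 1 fell (alone 5 and 1), camera adjusted p = 0.328, with hid (0.60 ± 0.18) and Diap1 (0.64 ± 0.17) (largest adjusted p = 0.0182), where hid promotes and Diap1 blocks cell death. Of the fat body and hemocyte genes, 0 of 8 rose and 3 fell (alone 0 and 3), camera adjusted p = 0.117, namely Hml (-4.46 ± 0.63), Lsp2 (-2.78 ± 0.54) and Glt (-1.93 ± 0.54 [CG9287]) (largest adjusted p = 0.0118). cac (-1.84 ± 0.35), comt (-1.71 ± 0.34) and repo (-1.24 ± 0.26 [CG7156]) (largest adjusted p = 0.00152) fell too, where cac and comt work in synaptic release and repo marks glia. gcm2 (1.51 ± 0.55) and nrv2 (0.71 ± 0.19) (largest adjusted p = 0.0463) of the glial genes rose.

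X genes had a median 0.15 below that of autosomal genes (camera adjusted p = 0.00369, adjusted p = 0.427 with an estimated correlation), and chromosome 4 genes shifted up (camera adjusted p = 0.000910, adjusted p = 0.580 with an estimated correlation). The X to autosome ratio was -2.91 ± 0.019 against -2.83 ± 0.051, lower by 5.40% (two-sided exact permutation p = 0.00583, adjusted p = 0.0408). Leaving out any 1 library except control male 1 lost the threshold (12 of 13, adjusted p from 0.0707 to 0.0884). Groups did not overlap for 6.49% of the genes tested (chance 0.117%).

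Did gastrulating females respond to mof depletion? In St7 females 959 genes rose and 1465 fell, but rises outnumbered falls with scaling on autosomal genes (1270 and 1217), with only the 2 groups in the fit (1309 and 1231) and without mof female 3 (965 and 941). Of 22 cell cycle genes 16 rose, as did the muscle gene sls and the glial regulator gcm. Hml of blood cells, Lsp2 of the fat body and comt of synapses fell.

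Highest among the rises were Slc45-1 (5.47 ± 1.20), CG32354 (5.41 ± 1.03 [Exo70]), bap (4.61 ± 0.68), C1GalTA (3.21 ± 0.57), Hsp70Bb (3.43 ± 0.62) and Argk1 (2.70 ± 0.28) (largest adjusted p = 0.00224), where Slc45-1 varied between libraries (21.7 ± 31.6 CPM). Deepest among the falls were Dhc98D (-6.81 ± 1.55), Inx5 (-6.09 ± 1.07), CG18586 (-4.29 ± 0.36 [CG5568]), Pask (-3.30 ± 0.40) and Sply (-3.30 ± 0.41) (largest adjusted p = 0.00289). Of the cell cycle genes, 16 of 22 rose and 0 fell (alone 18 and 0), camera up with adjusted p = 4.28e-07 and adjusted p = 0.370 with an estimated correlation, with aurA (0.85 ± 0.24 [CG12213]), dap (0.64 ± 0.19) and fzr (0.45 ± 0.10) (largest adjusted p = 0.0143). dap and fzr end cell cycles. roX1 (0.52 ± 0.14 [ec]), Clamp (0.47 ± 0.10 [CG42748]) and mle (0.45 ± 0.10) (largest adjusted p = 0.0101) rose among the MSL and roX genes. CrebA (1.36 ± 0.29), Tl (1.05 ± 0.20), hb (0.71 ± 0.21), gcm2 (2.09 ± 0.61), gcm (0.97 ± 0.26 [CG31709]), GATAe (1.28 ± 0.43), dsx (0.61 ± 0.16 [lds]) and sls (1.44 ± 0.41) (largest adjusted p = 0.0309) rose as well, where gcm sets glial and blood cell fate and sls builds muscle. Hml (-3.39 ± 0.76), Lsp2 (-2.71 ± 0.78), comt (-1.79 ± 0.40), repo (-1.59 ± 0.32 [CG7156]), p53 (-0.87 ± 0.21 [Gr94a]), Pgk (-0.75 ± 0.13 [Cwc25, Bacc]), aub (-0.79 ± 0.20 [TTLL4A]) and Rel (-0.75 ± 0.19 [Nmdmc]) (largest adjusted p = 0.0121) fell. Hml is a clotting protein of blood cells and Lsp2 a storage protein.

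X genes had a median 0.079 below that of autosomal genes (camera adjusted p = 0.194). Log2 fold changes lay below 0 for 61.15% of X genes and 54.26% of autosomal genes, against 66.62 and 49.63% in St7 males. Of the X genes that passed in the 2 sexes, 201 fell in each and 31 rose in each. The X to autosome ratio was -2.60 ± 0.047 against -2.56 ± 0.026 (two-sided exact permutation p = 0.124, adjusted p = 0.217). Chromosome 4 genes shifted up (camera adjusted p = 1.34e-06, adjusted p = 0.478 with an estimated correlation). The libraries of the groups stood apart for 19.02% of the genes tested (chance 0.952%).

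How did control males and females differ at gastrulation? The difference lay mostly on X: 463 genes were lower in males, 445 of them X genes, and 79 were higher. Sxl was lower in males, and msl-2, roX2, mof and Y-linked genes were higher. Control male 7 had 0 counts of kl-3 and kl-5 (under a floor of 3), with 48 Y-linked counts in all.

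msl-2 (2.001 ± 0.13), mof (1.80 ± 0.39), roX2 (1.87 ± 0.41), msl-3 (0.87 ± 0.076 [form3]), ben (0.74 ± 0.14), kl-3 (at least 31.5-fold higher), kl-2 (at least 19.3-fold higher) and FDY (3.55 ± 0.56) (largest adjusted p = 0.00419) were higher in males. Sxl (-1.94 ± 0.14), roX1 (-0.54 ± 0.13 [ec]), Rbcn-3B (-1.19 ± 0.17 [mip130]), CG2145 (-1.12 ± 0.16), sc (-0.73 ± 0.11 [CG32816]), upd1 (-0.56 ± 0.14) and CycD (-0.63 ± 0.11) (largest adjusted p = 0.0115) were lower, where sc and upd1 are X-linked signals of sex. Of the MSL and roX genes, 4 of 8 rose and 1 fell (alone 4 and 1), camera up with adjusted p = 1.397e-09 and adjusted p = 0.000428 with an estimated correlation. Of the sex determination genes, 0 of 14 rose and 3 fell (alone 0 and 4), camera down with adjusted p = 0.000162 and adjusted p = 0.00251 with an estimated correlation, and the submitters' sex call from msl-2, Sxl, tra and tra2 applies here. Of the Y-linked genes, 3 of 3 rose and 0 fell (alone 3 and 0), too few for camera. The X median lay 0.43 below that of autosomal genes (camera adjusted p = 1.68e-62, adjusted p = 4.97e-07 with an estimated correlation), and the X to autosome ratio was lower in males by 0.27 (two-sided exact permutation p = 0.00117). Groups did not overlap for 4.30% of the genes tested (chance 0.117%).

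Did the mof effect differ between sexes at gastrulation? No single gene passed, with 0 genes in edgeR, 0 in DESeq2 and 318 at unadjusted p. The difference for mof was -2.21 ± 0.62 (edgeR adjusted p = 0.9997) and for roX1 -0.40 ± 0.19. Of the neuronal genes, 0 of 9 rose and 0 fell (alone 0 and 1), camera down with adjusted p = 0.0380 and adjusted p = 0.819 with an estimated correlation. Among oxidative phosphorylation genes, 0 of 70 rose and 0 fell (alone 0 and 0), camera up with adjusted p = 0.00133 and adjusted p = 0.925 with an estimated correlation. The X median lay 0.065 below that of autosomal genes and the difference in X ratio had an exact permutation p of 0.766. Sex labels were permuted within each treatment, and the X ratio differed by sex in the controls, so this p cannot decide the question. Leaving out mof male 3 gave 1 gene.

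What did late male embryos show after mof depletion? In St15 males X-linked genes fell broadly, 1080 of 1696 lower and 19 higher. The roX RNAs, which scaffold the MSL complex, fell. msl-1, msl-2, msl-3, dgt1 and nsl1, of the MSL and NSL complexes, rose, while wds of the NSL complex fell. In all, 1714 genes rose and 1948 fell of 10684 tested.

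On X, roX1 (chromosome X, 3857230 to 3862697) went from 871 ± 23.2 to 270.2 ± 41.1 CPM and roX2 (chromosome X, 11579065 to 11580432) from 38.5 ± 0.857 to 14.4 ± 1.84. Their changes were roX1 (-1.69 ± 0.11 [ec]) and roX2 (-1.41 ± 0.14) (largest adjusted p = 5.42e-06). Of the MSL and roX genes, 5 of 8 rose and 3 fell (alone 5 and 3), camera adjusted p = 0.195, with a median of 0.23 and a mean of -0.59. msl-1 (0.56 ± 0.12), msl-3 (0.36 ± 0.084 [form3]), msl-2 (0.27 ± 0.081) and Clamp (0.26 ± 0.077 [CG42748]) (largest adjusted p = 0.0203) rose. Of the NSL complex genes, 4 of 6 rose and 1 fell (alone 4 and 1), camera adjusted p = 0.114, with dgt1 (0.44 ± 0.085 [Cad99C]) and nsl1 (0.34 ± 0.052) (largest adjusted p = 0.00128) rising and wds (-0.26 ± 0.10) (adjusted p = 0.04996) falling. The largest rises were Drsl5 (2.34 ± 0.39), CG13239 (2.32 ± 0.49), Hsp70Bb (2.31 ± 0.78), Cpr65Ea (2.07 ± 0.37), TwdlH (2.04 ± 0.53) and CG42792 (1.79 ± 0.21) (largest adjusted p = 0.0428). The largest falls were CG4594 (-3.92 ± 0.27), CG9391 (-3.34 ± 0.14), CG13947 (-2.86 ± 0.22), O-fut2 (-2.66 ± 0.18) and Nprl2 (-2.35 ± 0.11 [CG4872]) (largest adjusted p = 9.00e-07).

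Of the cuticle protein genes, 20 of 85 rose and 0 fell (alone 19 and 0), camera up with adjusted p = 7.55e-05 and adjusted p = 0.917 with an estimated correlation. Of the neuronal genes, 0 of 17 rose and 8 fell (alone 0 and 8), camera down with adjusted p = 0.0487 and adjusted p = 0.917 with an estimated correlation, with comt (-0.84 ± 0.090), cac (-0.44 ± 0.073) and futsch (-0.38 ± 0.060 [Gr2a]) (largest adjusted p = 0.000444) on X and VGlut (-0.36 ± 0.078 [CG18641]) (adjusted p = 0.00275) on 2L. Of the cytoplasmic ribosomal protein genes, 9 of 83 rose and 8 fell (alone 5 and 8), camera up with adjusted p = 0.0487, adjusted p = 0.917 with an estimated correlation and adjusted p = 0.0565 with the replicate block, and the fallen RpL7A (-0.31 ± 0.065), RpS6 (-0.30 ± 0.068) and RpL36 (-0.28 ± 0.076) (largest adjusted p = 0.0107) are X-linked. Of the oxidative phosphorylation genes, 1 of 71 rose and 11 fell (alone 1 and 11), camera adjusted p = 0.840, with a median of 0.067, a mean of -0.046 and ND-24 (-0.76 ± 0.090) and ND-20 (-0.71 ± 0.072) (largest adjusted p = 2.48e-05). Gapdh2 (-0.83 ± 0.080), Sxl (-0.63 ± 0.092), snf (-0.37 ± 0.085) and egr (-0.42 ± 0.068) (largest adjusted p = 0.00418) also fell. Among other named genes that rose were Ku80 (1.31 ± 0.13), Irbp (0.89 ± 0.19), Xrp1 (0.74 ± 0.095), RnrL (0.71 ± 0.063), Mcm5 (0.41 ± 0.10) and PCNA (0.37 ± 0.085) (largest adjusted p = 0.00774). The egg transcripts png (-3.76 ± 0.70) and cort (-1.47 ± 0.51 [cup, CG34310]) (largest adjusted p = 0.0393) fell, where control male 2 and mof male 1 carried egg RNA (bcd at 21.2 and 17.5 CPM).

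The X median lay 0.59 below that of autosomal genes (camera adjusted p = 8.07e-61, adjusted p = 1.30e-05 with an estimated correlation), and chromosome 3L shifted up (camera adjusted p = 0.0251, adjusted p = 0.0300 with an estimated correlation). The shift of 3L is relative to all other genes, the fallen X genes included, so it cannot be told apart from the fall of X. The X to autosome ratio was -2.95 ± 0.032 against -2.52 ± 0.0050, lower by 26.0%, and this design cannot reach p under 0.05 (two-sided exact permutation p = 0.1, its smallest, adjusted p = 0.217). No overlap between groups was seen for 44.3% of the genes tested (chance 10%).

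**Figure D4:**
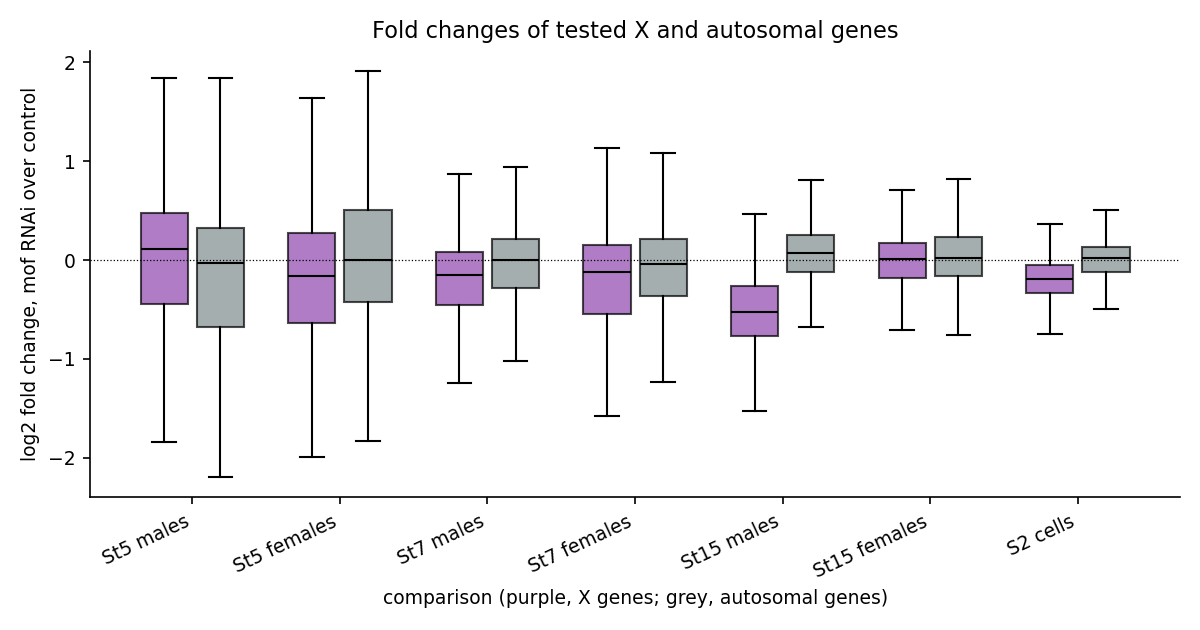
edgeR log2 fold changes of X genes (purple) and autosomal genes (grey) in each mof comparison, with boxes at the quartiles, a line at the median and whiskers to the most extreme gene within 1.5 interquartile ranges (outliers not drawn). X genes sit below autosomal genes in St15 males and S2 cells.

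Did late female embryos change too? In St15 females 1352 genes rose and 1425 fell, and of X genes 233 fell and 180 rose. Without control female 2 these were 346 and 1038, with 175 lower and 48 higher on X, and without control female 3 604 rose and 1192 fell. Cuticle, muscle and heat shock genes were among those that rose. roX2 rose at a low level with overlap between the groups, from 1.26 to 2.15 CPM in control females and 1.94 to 2.65 in mof females. roX1, msl-2 and Sxl did not pass.

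The top rises were Hsp70Bb (2.99 ± 0.81), Hsp70Ab (2.68 ± 0.79 [CG3281]), Prx6b (2.60 ± 0.55), TwdlH (2.19 ± 0.50) and Drsl5 (2.18 ± 0.39) (largest adjusted p = 0.0348). The steepest falls were CG4594 (-3.01 ± 0.22), S2P (-2.84 ± 0.22 [CG34229]), CG9391 (-2.75 ± 0.12) and PolG1 (-2.53 ± 0.14) (largest adjusted p = 1.78e-06), where PolG1 is the mitochondrial DNA polymerase. Of the cuticle protein genes, 28 of 85 rose and 2 fell (alone 33 and 2), camera up with adjusted p = 7.60e-10 and adjusted p = 0.956 with an estimated correlation. For muscle genes, 11 of 21 rose and 0 fell (alone 16 and 0), camera up with adjusted p = 0.00163 and adjusted p = 0.956 with an estimated correlation, with Zasp66 (1.23 ± 0.36 [Cdc6]), Act87E (0.67 ± 0.21) and Tm2 (0.29 ± 0.10) (largest adjusted p = 0.0474). For heat shock genes, 7 of 17 rose and 0 fell (alone 10 and 0), camera up with adjusted p = 0.00377 and adjusted p = 0.956 with an estimated correlation. Of the oxidative stress and detoxification genes, 7 of 21 rose and 0 fell (alone 9 and 0), camera up with adjusted p = 0.0115 and adjusted p = 0.956 with an estimated correlation, with GstD10 (0.63 ± 0.17) (adjusted p = 0.0150).

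Of the midgut genes, 3 of 10 rose and 1 fell (alone 3 and 1), camera adjusted p = 0.209, with Mal-A2 (1.398 ± 0.35) and Jon65Aiii (0.75 ± 0.25) (largest adjusted p = 0.0462). Of the fat body and hemocyte genes, 6 of 16 rose and 0 fell (alone 6 and 0), camera adjusted p = 0.158, with SPARC (0.48 ± 0.12) and vkg (0.44 ± 0.11) (largest adjusted p = 0.0153) of the basement membrane. Of the chitin and tracheal tube genes, 5 of 18 rose and 2 fell (alone 6 and 2), camera adjusted p = 0.401, with obst-E (1.23 ± 0.28) (adjusted p = 0.0111). Of the strain marker genes, 3 of 6 rose and 0 fell (alone 3 and 0), camera adjusted p = 0.230, with y (1.88 ± 0.51 [CG32816]) and v (0.74 ± 0.18) (largest adjusted p = 0.0236). Eaat1 (0.94 ± 0.30), Gs2 (0.58 ± 0.13) and repo (0.39 ± 0.090 [CG7156]) (largest adjusted p = 0.0451) of the glia rose, and Dcr-1 (-0.67 ± 0.067), Drice (-0.40 ± 0.093), Ku80 (-0.40 ± 0.12), Irbp (-0.54 ± 0.19) and her (-0.52 ± 0.074) (largest adjusted p = 0.0477) fell. roX2 (0.55 ± 0.17) (adjusted p = 0.0322) rose, and roX1 (-0.15 ± 0.11, adjusted p = 0.296), msl-2 (0.012 ± 0.081, adjusted p = 0.930) and Sxl (-0.22 ± 0.085, adjusted p = 0.0671) did not pass. mof female 3 held 1.90 Y-linked CPM (95% Wilson interval 1.39 to 2.58), where the other mof females held 0.0384 to 0.0946. Intervals of this kind cover counting error only. The mean log2 CPM of mitochondrially encoded genes was 6.91, 6.94, 7.76 and 7.31 in mof females 1 to 4, where controls had 7.33 to 7.88.

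The X median lay 0.015 below that of autosomal genes, and the X to autosome ratio was -2.43 ± 0.022 against -2.42 ± 0.013 (two-sided exact permutation p = 0.686, adjusted p = 0.686). The groups stood apart for 39.6% of the genes tested (chance 5.71%). The 2777 genes were 1384 and 1796 without control females 2 and 3, and without mof female 1 the difference in X ratio turned to 0.000678 (exact permutation p = 0.9).

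How did control males and females differ late in embryogenesis? The sexes were close, with 39 genes higher and 100 lower in males, 96 of the lower ones on X. The roX RNAs, msl-2 and the Y-linked FDY stood above females, and Sxl and dsx, which carries out somatic sex differentiation, below. FDY (8.42 ± 1.62), roX2 (4.54 ± 0.17), roX1 (4.22 ± 0.13 [ec]), CG42792 (2.28 ± 0.24), msl-2 (1.90 ± 0.086), RpL22-like (1.26 ± 0.28) and mof (1.17 ± 0.22) (largest adjusted p = 0.0478) were higher, and CG14795 (-1.99 ± 0.23 [inc]), CG3823 (-1.44 ± 0.21), Sxl (-1.12 ± 0.093), dsx (-0.87 ± 0.20 [lds]), ovo (-0.51 ± 0.11) and Gapdh2 (-0.38 ± 0.080) (largest adjusted p = 0.0485) were lower. Of the MSL and roX genes, 5 of 8 rose and 0 fell (alone 7 and 0), camera up with adjusted p = 5.49e-111 and adjusted p = 3.80e-06 with an estimated correlation. For sex determination genes, 0 of 13 rose and 2 fell (alone 0 and 3), camera down with adjusted p = 0.000244 and adjusted p = 0.288 with an estimated correlation. Of the innate immune genes, 1 of 7 rose and 0 fell (alone 2 and 0), camera up with adjusted p = 0.0437 and adjusted p = 0.362 with an estimated correlation. For strain marker genes, 0 of 6 rose and 0 fell (alone 0 and 0), camera down with adjusted p = 0.00540 and adjusted p = 0.288 with an estimated correlation.

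X genes had a median 0.075 below that of autosomal genes (camera adjusted p = 9.04e-07, adjusted p = 0.0257 with an estimated correlation), and the X ratio was lower in males by 0.10 (two-sided exact permutation p = 0.1, the smallest possible). The groups stood apart for 18.8% of the genes tested (chance 10%). The count of 139 was 63 and 54 without control females 3 and 4, and 58, 49 and 60 without control males 1, 2 and 4. It was 282 with DESeq2, 23 with the replicate block and 56 without the pools that hold egg RNA.

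Did the late effect of mof depletion differ between the sexes? It did for 1788 genes, 701 higher and 1087 lower in males, and 848 X genes were lower against 1 higher. roX1 and roX2 had lower changes in males, and genes of synapses and of oxidative phosphorylation on X were lower too. Ku80 and Irbp rose in males and fell in females.

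CG42792 (2.29 ± 0.33), Ku80 (1.71 ± 0.18), PolQ (1.60 ± 0.37 [CG12279]), Irbp (1.44 ± 0.27), dgt1 (0.55 ± 0.12 [Cad99C]) and her (0.45 ± 0.11) (largest adjusted p = 0.0138) were higher, and Fst (-2.62 ± 0.79 [Dh44]), roX2 (-1.96 ± 0.22), CG3568 (-1.84 ± 0.19), roX1 (-1.53 ± 0.15 [ec]), mof (-1.38 ± 0.33), Gapdh2 (-0.96 ± 0.11), Hex-A (-0.40 ± 0.10) and Sxl (-0.40 ± 0.13) (largest adjusted p = 0.0462) were lower. Of the neuronal genes, 0 of 17 rose and 4 fell (alone 0 and 4), camera down with adjusted p = 0.00233 and adjusted p = 0.573 with an estimated correlation, with comt (-0.98 ± 0.12) and cac (-0.52 ± 0.10) (largest adjusted p = 0.00369). Among oxidative phosphorylation genes, 0 of 71 rose and 10 fell (alone 0 and 10), camera down with adjusted p = 0.00233 and adjusted p = 0.911 with an estimated correlation, with ND-20 (-0.85 ± 0.10) and ND-24 (-0.79 ± 0.12) (largest adjusted p = 0.000813). Of the RNA interference genes, 2 of 8 rose and 0 fell (alone 3 and 0), camera up with adjusted p = 0.0212 and adjusted p = 0.573 with an estimated correlation, with drosha (0.50 ± 0.092) and Dcr-1 (0.50 ± 0.10) (largest adjusted p = 0.00379). The X median lay 0.55 below that of autosomal genes (camera adjusted p = 1.96e-68, adjusted p = 6.53e-06 with an estimated correlation). Chromosome 3L had a median of 0.055 and a mean of -0.024 (camera adjusted p = 0.0182, adjusted p = 0.0187 with an estimated correlation). All autosomal genes had a median of 0.055 too. camera sets an arm against all other genes, the lowered X genes included, so this call does not show a change particular to 3L. The difference in X ratio had an exact permutation p of 0.0571, from sex labels permuted within each treatment, which does not test the difference in mof effect alone. The count was 2946 without mof male 4, with 1509 higher and 1437 lower, and without control male 2 972 were higher and 877 lower. mof male 4 had a mean log2 CPM of 6.5405 over mitochondrially encoded genes, where the other St15 males had 7.36 to 7.90.

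Did S2 cells, a male line, respond to mof dsRNA? X-linked genes fell, 589 of 1593 lower and 39 higher, and roX2 fell, while mof RNA itself did not pass. In all, 986 genes rose and 1275 fell of 9676 tested, and 14 rose and 82 fell by at least 2-fold. Of 22 cell cycle genes 11 rose. Of 10 neuronal genes 5 fell, not tested apart from X, where comt and cac lie.

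Here roX2 went from 3986 ± 256 to 1951 ± 123 CPM (-1.03 ± 0.064, edgeR adjusted p = 5.01e-06). roX1 (-0.48 ± 0.20, adjusted p = 0.100) and msl-2 (0.082 ± 0.047, adjusted p = 0.234) did not pass. For MSL and roX genes, 1 of 8 rose and 1 fell (alone 1 and 1), camera adjusted p = 0.544, with a median of 0.039 and a mean of -0.15. The largest rises were CG6472 (1.56 ± 0.13 [CG8910]), Nep4 (1.28 ± 0.12), fz (1.15 ± 0.12 [CG13482]) and Smyd4-3 (1.11 ± 0.082) (largest adjusted p = 9.73e-05), where fz is a Wnt receptor. The largest falls were CG7997 (-2.01 ± 0.15), Rpt3R (-1.64 ± 0.12 [Alg12]), Fign (-1.63 ± 0.081 [CG3277]), Hexo1 (-1.26 ± 0.10 [CG15012]) and Nek2 (-1.25 ± 0.094) (largest adjusted p = 3.51e-05). Of the cell cycle genes, 11 of 22 rose and 1 fell (alone 14 and 2), camera up with adjusted p = 0.00936 and adjusted p = 0.189 with an estimated correlation, with stg (0.40 ± 0.056), Cdk2 (0.27 ± 0.045 [CG17267]) and Cdk1 (0.23 ± 0.051) (largest adjusted p = 0.00716) up and CycD (-0.40 ± 0.050) (adjusted p = 0.000448) down. Of the oxidative phosphorylation genes, 19 of 73 rose and 6 fell (alone 24 and 8), camera up with adjusted p = 0.0183 and adjusted p = 0.856 with an estimated correlation, with ATPsyndelta (0.49 ± 0.050 [CG2962]) (adjusted p = 0.000107) up and ND-20 (-0.29 ± 0.061) and ND-24 (-0.32 ± 0.085) (largest adjusted p = 0.0216) down. Of the neuronal genes, 0 of 10 rose and 5 fell (alone 0 and 7), camera down with adjusted p = 0.0183 and adjusted p = 0.481 with an estimated correlation, with comt (-0.74 ± 0.14), cac (-0.72 ± 0.17) and elav (-0.37 ± 0.083 [arg]) (largest adjusted p = 0.0122). Of the mitochondrially encoded genes, 0 of 10 rose and 0 fell (alone 0 and 0), camera down with adjusted p = 0.0211 and adjusted p = 0.856 with an estimated correlation, with a median of -1.10. mof dsRNA library 1 had a mean log2 CPM of 2.61 over these genes, where the other S2 libraries had 5.09 to 5.89. Of the innate immune genes, 3 of 21 rose and 4 fell (alone 3 and 4), camera adjusted p = 0.957, with AttB (0.25 ± 0.057) and DptB (0.24 ± 0.053 [CG43109]) (largest adjusted p = 0.00920) up and CecA1 (-0.27 ± 0.060), CecB (-0.34 ± 0.065) and CecC (-0.55 ± 0.13) (largest adjusted p = 0.0339) down, all antimicrobial peptides. Of the ovarian follicle cell genes, 0 of 6 rose and 0 fell (alone 0 and 0), camera adjusted p = 0.816, and too few were tested in embryos. msl-3 (0.19 ± 0.049 [form3]) and MBD-R2 (0.15 ± 0.045) (largest adjusted p = 0.0297) rose, and Sxl (-0.59 ± 0.080), zld (-0.50 ± 0.10), AGO2 (-0.25 ± 0.048 [CG7739]) and Hsp68 (-0.15 ± 0.048 [CG6000]) (largest adjusted p = 0.0410) fell.

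The X median lay 0.21 below that of autosomal genes (camera adjusted p = 9.21e-18, adjusted p = 0.0228 with an estimated correlation). The X to autosome ratio was -2.72 ± 0.0077 against -2.51 ± 0.026, lower by 13.2%, and this design cannot reach p under 0.05 (two-sided exact permutation p = 0.1, its smallest, adjusted p = 0.217). Groups did not overlap for 41.1% of the genes tested (chance 10%). Without control 3 the count was 1375 and without mof library 2 it was 1317.

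**Figure D5:**
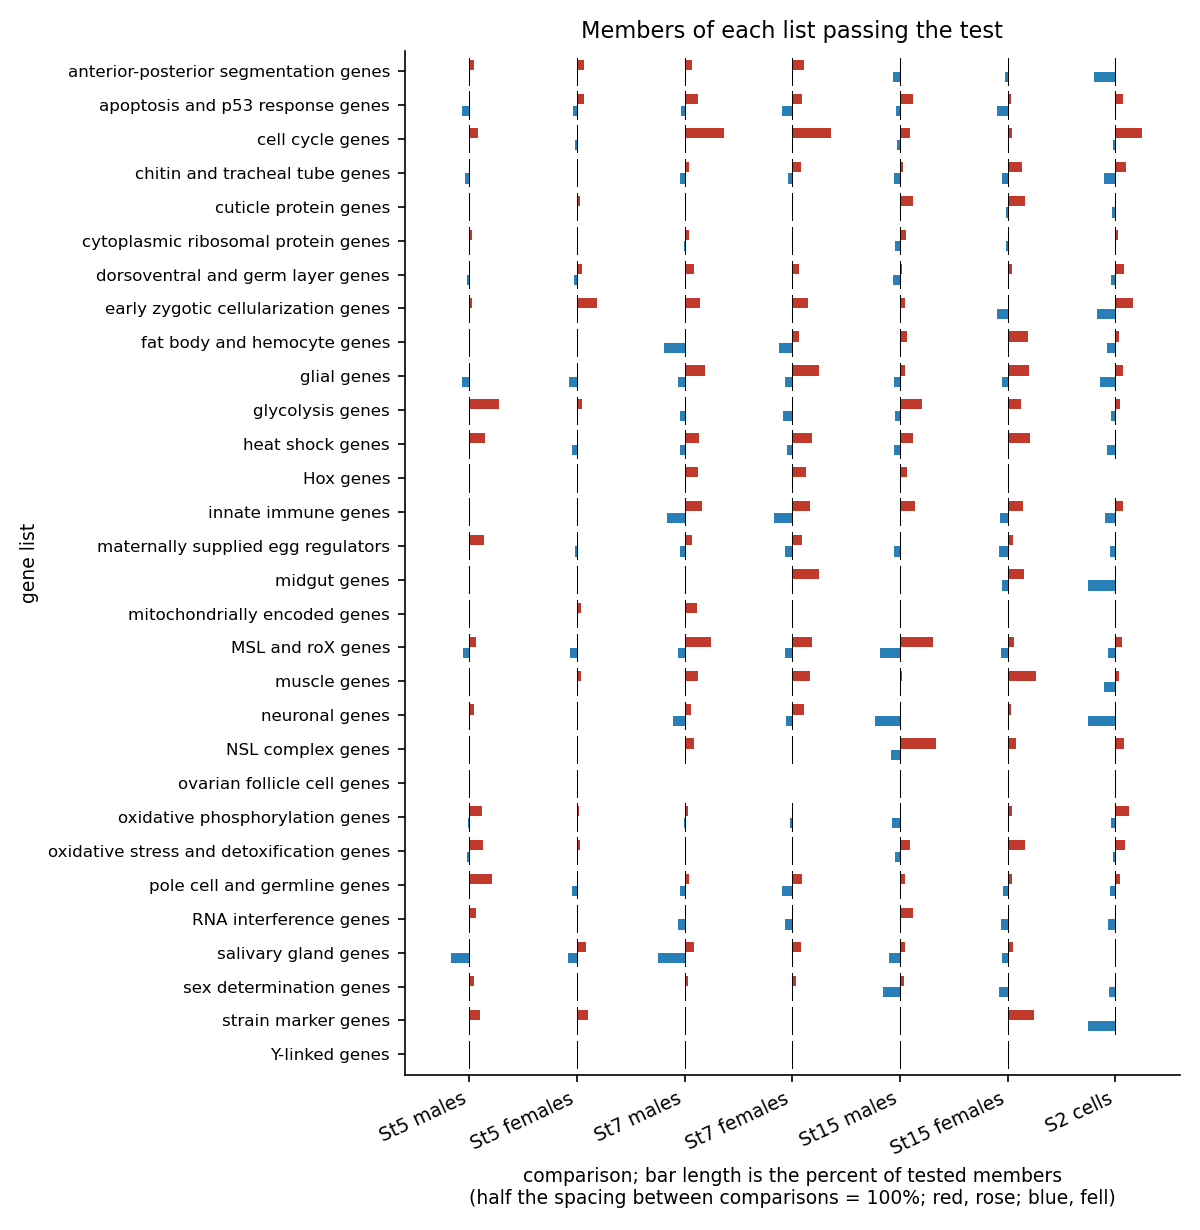
Percent of tested members of each gene list that rose (red) and fell (blue) in each mof comparison, with bars of a common scale up to 100%. Cell cycle genes have the longest red bars in St7 males and in St7 females.

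Which changes were shared between sexes, stages and cells? Across 12 pairs of comparisons, log2 fold changes were ranked against each other over the genes tested in each of the pair, and genes are not independent replicates. St7 males and females had a Spearman correlation of 0.80. All 1555 genes that passed in the 2 sexes moved the same way, with 1003 lower where 223 would be expected if the 2 were independent and 552 higher where 90.9 would. A difference between the mof and control stocks, or in age between their embryos, could be shared by the sexes as well. Sharing between embryo groups does not separate these from mof depletion. At St7 the mean log2 CPM of egg regulators was 3.83 to 3.92 in mof males and 3.87 to 4.16 in control males. In females it was 3.69 to 3.94 and 3.84 to 4.18. With the egg regulators as a covariate 481 genes rose and 1030 fell in St7 males, and 626 and 1263 in St7 females. At St15 the correlation was 0.41 with 1173 of 1281 genes in the same direction, and at St5 it was 0.34 with 161 of 163. Between stages it was lower. In males it was 0.26 for St5 and St7, 0.027 for St5 and St15 (250 of 484 genes in the same direction) and 0.26 for St7 and St15. In females it was 0.030, 0.040 and 0.19 for the same pairs of stages. S2 cells and St15 males had 0.41, or 0.32 over autosomal genes, and 451 X genes were lower in the 2 where 402 would be expected. With S2 cells, St5 males had 0.062 and St7 males 0.18.

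mof, Qsox1 (chromosome 2R, 13231758 to 13235296), CG14102 (chromosome 3L, 19798975 to 19801291) and Ir76a (chromosome 3L, 19799278 to 19803427) were lower in all 6 embryo comparisons, where CG14102 and Ir76a overlap each other. The log2 fold changes of Qsox1, males before females from St5 to St15, were -0.75, -1.08, -0.44, -0.64, -0.50 and -0.29. pths (chromosome 2L, 21143229 to 21145146) was higher in all 6, by 0.53, 0.91, 0.26, 0.27, 0.86 and 0.27. In S2 cells CG14102 (-0.47), Ir76a (-0.54), Qsox1 (-0.21) and pths (0.22) passed too.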

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

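The tests of explanations and the splits of libraries in this part were chosen after the result was seen, except the tests of library size and of a lost segment of X, while the comparisons they refer to were planned.

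In the St5 libraries labelled mof male 1 and 2, Y-linked genes had 3 and 0 counts (0.0902 CPM, 95% Wilson interval 0.0307 to 0.265, and under a floor of 0.0940). At the lowest rate among the other St5 males 181 were expected at the lower depth, so low depth does not explain this. Male embryos without a Y would keep low Sxl, but Sxl stood at 400.0 CPM or more against at most 84.1 in other libraries labelled male. X genes held 15.14 and 15.02% of counts (95% Wilson interval of the lower 15.0107 to 15.0359), above the other St5 males (at most 14.9%) and below the St5 females (15.75 to 17.25%), and msl-2 stood at 73.4 and 65.5 CPM against 47.5 to 228 in the other St5 males, 1.33 to 11.7 in St5 females and 43.6 to 67.7 in St7 females. The St5 females are no even standard for the X share, since bcd stood at 220 to 265 CPM in them and at 11.4 and 10.6 in these 2 libraries. St7 control females held 14.1 to 14.8% of counts on X. The X share therefore cannot decide whether these embryos are female. The Y-linked counts and Sxl of these 2 libraries argue against male embryos, while msl-2 and the X share do not decide. Genotyping or resequencing the same RNA could test it.

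St5 control males and females differed in 5642 genes. Of 25 egg regulators 20 were lower in males, which is in line with younger embryos among those labelled female. Sex alone would put the difference on X, but 82.4% of the genes passing were autosomal, against 13.5% at St7. Library size does not account for it, since 5584 genes passed after thinning all libraries to the smallest. Embryos timed from the onset of cycle 14 could separate age from sex.

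In S2 cells X genes fell while mof RNA did not pass (-0.17 ± 0.16, edgeR adjusted p = 0.491). An exchange of 1 or 2 libraries between the groups is excluded, as 0 libraries lay inside the other group's range of X ratio or roX2. An exchange of all libraries would turn every change round, yet 593 of the 676 autosomal genes that passed in S2 cells and in St15 males, where mof RNA fell, moved the same way, and the Spearman correlation with St15 males was 0.24 to 0.33 in 9 pairs of S2 libraries, so it stays open only if mof depletion acts in S2 cells in the opposite sense. Loss of a segment of X is excluded too, as 100% of 24 windows lay below the autosomes, with medians from -0.50 to -0.11 against 0.022. Reads of the mof dsRNA itself might hide a fall of mof RNA, and coverage along mof outside the dsRNA, or a blot of MOF protein, could test this.

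Splits of the libraries into other groups gave these values, each as the share of splits at or above the real result, the true grouping included. For genes passing these were 1 of 35 in St5 males (1260, highest other 539), 1 of 100 in St7 males (2196, 201) and St7 females (2424, 758), 1 of 100 in St7 controls (542, 41) and 1 of 35 in St15 females (2777, 0). For the difference between sexes they were 100 of 100 at St7 (0, highest other 499) and 3 of 100 at St15 (1788, 2677). These splits shuffled sex labels within each treatment, so sex differences shared by the treatments enter them too. With 0 real genes the St7 share was fixed in advance and says nothing. St15 males (3662, 0), St15 controls (139, 1) and S2 cells (2261, 0) gave 1 of 10, and 10 splits are too few for a share under 0.05. For the X median they were 3 of 35 in St5 males (0.14, highest other 0.17), 1 of 100 in St7 males (-0.15, 0.13), 3 of 100 in St7 females (-0.079, 0.092) and 8 of 35 in St15 females (-0.015, 0.022). In St15 males (-0.59, 0.22) and S2 cells (-0.21, 0.080) the X median gave 1 of 10, with the same limit.

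Of 77 tests for a library apart from its group 4 passed, where chance gives about 1 in 20. St5 control male 3 held bcd at 14.6 CPM, against 3.25 to 3.87 in the other control males. St5 mof male 1 held w at 3.67 CPM, against 92.5 to 110 in the other mof males. St7 mof female 4 held Sxl at 899 CPM, against 556 to 580 in the other 3. St15 mof female 3 held 1.90 Y-linked CPM, against 0.0384 to 0.0946 in the other 3. By sex label the mof effect differed for 11 genes at St5 and 1788 at St15.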

How the results depend on the processing

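The tests that leave out libraries of doubtful sex or egg RNA, and the maternal covariate, were chosen after the result was seen.

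The counts of the St5 mof comparisons, of the St5 difference between sexes and of the St15 controls varied widely. The St5 controls (5642 genes) stayed at 3899 to 6220. In St5 males the 1260 genes were 2058 with DESeq2, 752 at 10 CPM or more, 741 with the replicate block, 823 with only the 2 groups, 586 without the libraries of high Sxl and 2245 without the 3 libraries of doubtful sex or age. Leaving out 1 library gave 509 to 2461. In St5 females the 368 genes were 989 with DESeq2, 190 with the block, 1965 with only the 2 groups and 43 to 225 without 1 library. The St5 difference between sexes (11 genes) was 337 with DESeq2, 6 with TMM on autosomal genes (5 higher and 1 lower), 3 at 10 CPM or more, 0 with the replicate block and 0 to 140 without 1 library. The St7 difference between sexes stayed at 0 to 1. St15 controls (139 genes) gave 282 with DESeq2, 23 with the block, 56 without the pools with egg transcripts and 49 to 123 without 1 library. Without 1 library St15 females gave 1384 to 2653, the St15 difference between sexes 1218 to 2946, and S2 cells 1317 to 2186.

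With TMM on autosomal genes the balance of rises and falls moved by over 10 points in St7 females (1270 and 1217), in St15 males (1236 and 2260) and in the St5 difference (5 and 1). With only the 2 groups St7 females gave 1309 and 1231. The St5 female X median of -0.17 was -0.031 with no low count filter (camera adjusted p = 0.0749), -0.18 with only the 2 groups (camera adjusted p = 0.105), -0.12 with the maternal covariate (camera adjusted p = 0.316) and -0.18 to -0.094 without 1 library. The X ratio difference in St5 males turned to -0.000488 without the libraries of high Sxl (exact permutation p = 1). In St7 males it was -0.095 to -0.070 without 1 library, and in St15 females -0.017 to 0.000678. The Sxl change in St5 males was -0.065 without the libraries of high Sxl and -0.21 without the 3 libraries.

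Of 102 list calls, 15 stayed with an estimated correlation, and with the replicate block 2 were lost (muscle genes in St7 males, camera adjusted p = 0.0605, and ribosomal protein genes in St15 males, camera adjusted p = 0.0565) and 6 were gained. Of the values of named genes over the fixed alternatives, 11971 stayed, 1607 were weaker and 13 stronger. The correlation of residuals within a replicate number was between -0.30 and 0.23. The own number was the best match for 1 of 4 in St5 males, 1 of 6 in St7 males and 0 of 3 in St15 females, but for 3 of 3 in St15 males (0.065 to 0.18) and 2 of 3 in S2 cells, where pairing stays open and the block gave 3395 and 2174 genes. Replicates differed by more than counting error, with a chi-square per degree of freedom of at least 6.14.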

Other observations

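The tests in this part were planned, and only the choice of what to print was made after the result was seen.

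In St7 males, of the mitochondrially encoded genes, 3 of 13 rose and 0 fell (alone 5 and 0), camera up with adjusted p = 0.0149 and adjusted p = 0.580 with an estimated correlation, with mt:CoIII (0.38 ± 0.084 [mt:ATPase6]) (adjusted p = 0.00248). Of the cytoplasmic ribosomal protein genes, 7 of 81 rose and 1 fell (alone 1 and 0), camera up with adjusted p = 4.90e-07 and adjusted p = 0.580 with an estimated correlation. Of the early zygotic cellularization genes, 5 of 17 rose and 0 fell (alone 5 and 0), camera up with adjusted p = 0.0303 and adjusted p = 0.192 with an estimated correlation, with Traf4 (0.41 ± 0.086), Tom (0.35 ± 0.075) and Ocho (0.53 ± 0.14) (largest adjusted p = 0.0101), while their mean log2 CPM was 4.45 ± 0.21 against 4.48 ± 0.11 in control males. In St15 controls no heat shock gene passed between the sexes (0 of 17 rose and 0 fell (alone 0 and 0), camera adjusted p = 0.000319, adjusted p = 0.692 with an estimated correlation), and no cuticle protein gene did (0 of 85 rose and 0 fell (alone 0 and 0), camera adjusted p = 9.52e-07, adjusted p = 0.640 with an estimated correlation, mean log2 CPM 2.06 ± 0.41 in males and 2.32 ± 0.40 in females). In St7 females Msp300 (0.89 ± 0.24), nrv2 (0.999 ± 0.21) and E(spl)m7-HLH (1.06 ± 0.30) rose (edgeR adjusted p of at most 0.0113), while 4 of 12 muscle genes rose and 0 fell (alone 5 and 0), 4 of 8 glial genes rose and 1 fell (alone 4 and 1), and neither list was called (camera adjusted p = 0.1225 for each).

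In St15 females Xrp1 (0.43 ± 0.089) rose while Ku80 (-0.40 ± 0.12) and Irbp (-0.54 ± 0.19) fell (edgeR adjusted p of at most 0.0477). The sexes differed for Ku80 by 1.71 ± 0.18 and for Irbp by 1.44 ± 0.27 (edgeR adjusted p of at most 0.00288). In St5 males Xrp1 and Irbp fell, and in St15 males they rose. aub, which acts in the germline against transposons, was at 0.69 ± 0.15 in St5 males and at -0.79 ± 0.20 in St7 females. Hml was at -4.46 ± 0.63 in St7 males and at 0.29 ± 0.064 in S2 cells, where edgeR's adjusted p was 0.00788.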
